A study of Mus with 8 samples.

How the data were processed

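RNA sequencing libraries from mouse uterus at pseudopregnancy day 6 were compared between 4 controls and 4 uteri labelled as deficient for PGR in the myometrium. Per the labels, RNA was extracted with TRIzol. Per the submitters' processing notes, the tools were HISAT2 2.2.1 and HTSeq 0.10.0 and the genome build was mm10; the settings of these tools, including strand, are not given in the sources used here. The authors deposited a single table of whole-number counts for 31269 gene symbols in 8 libraries, with no normalization. Column names were matched to the sample titles. Of the symbols, 22353 were found in a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, which was used for coordinates and older symbols.

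Total counts per library ran from 70296369 to 72364750. Every pair of libraries differed by more than counting noise (smallest chi-square per degree of freedom 48.6, between control libraries 1 and 3), so no library was taken for a second copy of another. This covers counting error only and does not show that the 8 came from separate animals.

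Genes were filtered with filterByExpr, which left 17629, and scaled with TMM. Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3) with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 differences are deficient over control, and their SE was taken from the size of the difference and its F value. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists with at least 5 tested genes. Library means of each list were compared by a two-sided exact permutation test.

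Before the data were examined, 31 gene lists were fixed, and 30 were tested; the symbols of the mitochondrially encoded messenger RNAs had no match in the table, so that list is not analysed here. The lists hold markers of muscle, epithelial, gland, stromal, vascular, immune and other cell types and genes of hormone response, contraction, matrix, inflammation and metabolism. Some genes stand in more than 1 list, such as Lif, Hand2 and Krt19. Named genes were also fixed by a rule: Pgr, then up to 12 genes per direction with the largest change among those past the threshold with no overlap between groups, then up to 4 members per list with the smallest p. No gene met the second part, as edgeR called 0 genes against 4372 at an unadjusted p under 0.05, 2488 called by DESeq2 and 2 by limma-voom. The rule gave 117 genes, of which 114 were carried on and examples are printed, and single values of a few genes are not reported here, though they stay in the counts and list tests; other named genes are said to be chosen after their values were seen.

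Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile, library totals), no filter or 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, robust=TRUE, a test against a fold of 1.2, the replicate number as a block, leaving out each library, an estimated correlation for camera, and fry. A fit with legacy=FALSE, DESeq2 without each library, and all counts without libraries 2 and 3 labelled deficient were added after seeing the data. All 35 splits of the 8 libraries into 4 and 4 were refitted.

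The tests were tried on simulated counts with 67, 67 and 66 genes changed 1.5, 2 and 4 times, at the means, library sizes and dispersions of these libraries, over 17482 genes. For this comparison edgeR recovered 17.9%, 70.1% and 90.9% of genes changed 1.5, 2 and 4 times, with 5 false calls. DESeq2 recovered 43.3%, 89.6% and 93.9%, with 51 false calls. The simulated genes were independent of each other, and each had the same dispersion in both groups. The real groups differed in their spread, so these shares do not give the power of the real test. A lack of edgeR calls therefore does not show that few genes changed 4 times.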

Results

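Uterine RNA from mice at pseudopregnancy day 6 was measured by RNA sequencing in 8 libraries. Pseudopregnancy is the progesterone-dominated state that follows a sterile mating. Per the labels, 4 libraries were controls and 4 came from uteri with a deficiency of the progesterone receptor (PGR) in the myometrium, the smooth muscle wall. The values were read counts per gene over uterine tissue, which also holds epithelium, stroma, vessels and immune cells. The labels describe the tissue as lying around implantation sites, although pseudopregnancy involves no embryos, so which part of the uterus was taken, or whether the stage is as stated, is left unsettled. Total counts were 70296369, 71020306, 71303026 and 70747098 in control libraries 1 to 4, and 71377993, 72364750, 71486567 and 72182652 in libraries 1 to 4 labelled deficient. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these libraries. The comparison asks how uterine gene expression differs between the controls and the uteri labelled as deficient for PGR in the myometrium.

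Pgr, the gene for the targeted receptor, was not lower in the libraries labelled deficient. It lies on chromosome 9 from 8898900 to 8968611 (GRCm38.p6). Its level was 156.5 ± 22.8 CPM (TMM-scaled counts relative to library size; SD, n = 4) in the controls and 176.9 ± 12.1 CPM (SD, n = 4) in the libraries labelled deficient. The log2 difference of deficient over control was 0.18 ± 0.11 (SE), a 1.13-fold ratio with a 95% interval from 0.950 to 1.35. In edgeR the adjusted p was 0.338, and a two-sided exact permutation test gave p = 0.2, where the smallest possible p is 0.0286. Counts cover the whole gene and all cell types, so a loss in muscle cells alone, or of part of the gene, is not separated by this measure. Because Pgr counts neither bear out the label nor contradict it, the group is called "labelled deficient" throughout. Every direction given here rests on the label alone.

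**Figure D1:**
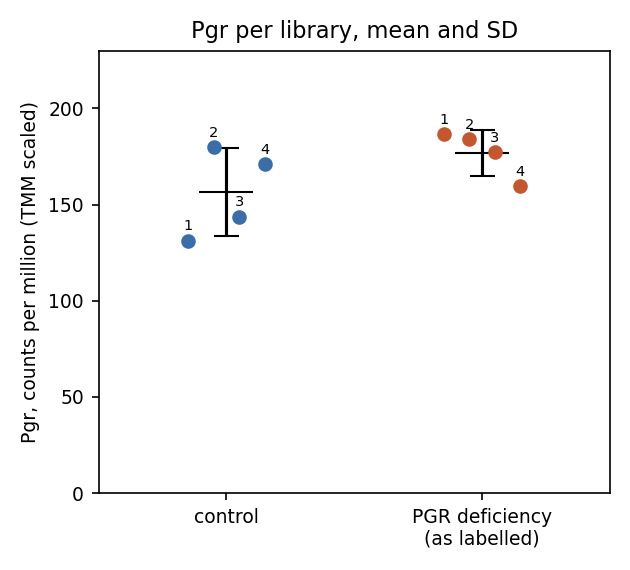
Pgr in each of the 8 libraries, in TMM-scaled CPM on an axis from 0, with replicate numbers beside the points; black bars give the mean and SD of 4 libraries. The libraries labelled deficient lie at 186.6, 183.9, 177.3 and 159.7 CPM, and the controls at 131.3, 180.0, 143.8 and 170.9 CPM.

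Between the groups, the list means of macrophage, lymphocyte and inflammation genes were higher in the libraries labelled deficient, and those of contraction and relaxation signalling were lower. Gene lists fixed before the data were examined and tested numbered 30. Random placement of the libraries would put all 4 libraries labelled deficient on one side of all 4 controls in 0.857 of them. The means of 5 lists did so. These were macrophage and monocyte markers (mean log2 difference 0.53), lymphocyte and natural killer cell markers (0.79), inflammatory cytokines and NF-kB targets (0.81), uterine activation and contraction signalling (-0.33), and smooth muscle relaxation and quiescence signalling (-0.22). Each had a two-sided exact permutation p of 0.0286, before adjustment over the 30 lists. Separation was common beyond these lists, at 16.3% of single genes. Of 10000 random lists matched on expression to a list of 18 genes described below, 7.83% separated the groups downward alone. The 5 lists are thus not shown to separate more often than other lists would. Camera called all 5 with its preset correlation and none with an estimated correlation (adjusted p from 0.488 to 0.566).

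No single gene passed the main test. Of 17629 genes tested, edgeR's quasi-likelihood test called 0 at the adjusted p threshold of 0.05 (smallest adjusted p 0.0715), and 4372 genes (24.8%) had an unadjusted p under 0.05 where 881 would by chance. Of these, 2295 were higher and 2077 lower in the libraries labelled deficient. DESeq2 called 2488 genes (1306 higher, 1182 lower) and limma-voom called 2. On simulated counts DESeq2 made 51 false calls and edgeR 5. In 2868 genes (16.3%) the 4 libraries of one group lay beyond all 4 of the other, where chance gives 2.86%. On leaving out 1 library, genes at an unadjusted p under 0.05 ran from 2896 (without control library 4) to 5471 (without library 4 labelled deficient), and DESeq2 calls from 927 to 3961 without the same libraries, with 1328 without control library 1 and 1531 without library 2 labelled deficient. Without libraries 2 and 3 of the group labelled deficient, an alternative added after seeing the data, edgeR called 0, 3325 had an unadjusted p under 0.05 and DESeq2 called 1461.

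The genes with the smallest p in edgeR, named after their values were seen, were Slc10a2, Cabp7 and Ecel1, all at adjusted p = 0.0715. Ecel1, a membrane metallopeptidase, measured 0.119 ± 0.132 CPM in controls and 8.93 ± 3.09 CPM in the libraries labelled deficient (SD, n = 4). Slc10a2, the ileal bile acid transporter, measured 1.18 ± 0.343 CPM in controls and 0.0349 ± 0.0323 CPM in the other group. Cabp7, a calcium-binding protein, measured 0.0103 ± 0.0132 CPM in controls and 0.557 ± 0.0569 CPM in the other group, a low level in both.

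The list of uterine activation and contraction signalling ranked lower in the libraries labelled deficient, though its receptors went both ways. Of 29 tested genes of uterine activation and contraction signalling, 20 had a negative difference, 0 passed over all genes, and 2 passed when adjusted over the list alone. These were Ptger3, a prostaglandin E2 receptor (log2 difference -1.34 ± 0.23 SE), and Ednrb, an endothelin receptor (-1.13 ± 0.23). Agtr1a, an angiotensin II receptor, was at -0.78 ± 0.21 and Adra1b, an adrenergic receptor, at -1.48 ± 0.44, neither past the threshold, although all 4 libraries labelled deficient lay below all controls for each of these 4 genes. Of the other receptors, chosen for mention after their values were seen, Oxtr, the oxytocin receptor, was at 1.03 ± 0.60, Tbxa2r at 0.26 ± 0.14, Ptger1 at 0.11 ± 0.08 and Ednra at -0.03 ± 0.09, while Ptgfr, a prostaglandin F receptor, was at -1.02 ± 0.55, none past the threshold. Camera called the list lower (adjusted p = 0.00233; adjusted p = 0.488 with an estimated correlation). The call held without libraries 2 and 3 (mean -0.25, adjusted p = 0.00288 with the preset correlation). Adjustment over a list alone, here and below, does not adjust over the 30 lists. Among all genes 24.8% had an unadjusted p under 0.05, and how often members of random lists would pass was not tested. Such passes therefore do not set a list apart from other genes.

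Relaxation signalling moved the same way. Of 30 tested genes 25 had a negative difference, 0 passed over all genes, and 2 passed when adjusted over the list alone: Pde5a, the cyclic GMP phosphodiesterase (-1.17 ± 0.28), and Ramp1, a subunit of the CGRP receptor (-0.44 ± 0.09). Camera gave an adjusted p of 0.00517 (adjusted p = 0.566 with an estimated correlation), and 0.126 without libraries 2 and 3, where the mean was -0.15. The contractile apparatus list had 24 of 27 members with negative differences, a mean of -0.20 and an adjusted p of 0.00234 (adjusted p = 0.651 with an estimated correlation). Its library means overlapped, at -0.27, -0.17, -0.09 and -0.21 in libraries 1 to 4 labelled deficient against -0.28, 0.16, -0.10 and 0.22 in the controls (two-sided exact permutation p = 0.257). Its members overlapped between groups in most cases: 4 of 27 lay wholly below the controls, and 1, the intermediate filament gene Synm (-0.73 ± 0.16), passed when adjusted over the list alone, against 0 over all genes. Pgm5 was at -0.38 ± 0.10 and Actn1, in the other direction, at 0.27 ± 0.09. Skeletal muscle markers were also lower (7 of 7 negative, mean -0.53, adjusted p = 0.00448, or 0.488 with an estimated correlation). Acta1 at -0.61 ± 0.17 and Actn3 at -0.46 ± 0.14 were the 2 that passed when adjusted over the list alone, against 0 over all genes. The library means of this list overlapped, with library 3 labelled deficient at -0.19 and control library 1 at -0.21 (two-sided exact permutation p = 0.0571).

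Of the immune cell lists, those of macrophages and lymphocytes were higher in the libraries labelled deficient, while the granulocyte and mast cell list, given below, was not called. Among macrophage and monocyte markers 18 of 20 had positive differences, 8 lay wholly above the controls and 10 passed when adjusted over the list alone, against 0 over all genes. Examples are Mrc1, the mannose receptor (1.03 ± 0.23), Fcgr1, an Fc receptor (1.24 ± 0.29), and the complement gene C1qc (0.51 ± 0.13). Camera gave an adjusted p of 3.81e-07 (adjusted p = 0.517 with an estimated correlation). Lymphocyte and natural killer markers had 20 of 22 positive differences and an adjusted p of 1.97e-05 (adjusted p = 0.488 with an estimated correlation), though 0 members passed over all genes or adjusted over the list alone; Gzma, a granzyme, was at 1.98 ± 0.54 and Cd79b, of the B cell receptor, at 1.00 ± 0.23. Both lists kept their call without libraries 2 and 3, with means of 0.26 and 0.83.

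The inflammatory and interferon-stimulated lists were called higher as well with camera's preset correlation, and not with an estimated one. Of 24 inflammatory genes 22 had positive differences (adjusted p = 0.00448; adjusted p = 0.517 with an estimated correlation), and 2 passed when adjusted over the list alone against 0 over all genes: Lif, a cytokine needed for implantation (2.88 ± 0.59), and Saa3, an acute phase protein (2.29 ± 0.55). Of 26 interferon-stimulated genes 25 had positive differences with a mean of 0.82, and 16 passed when adjusted over the list alone against 0 over all genes, among them Stat2 (0.71 ± 0.20) and Zbp1 (1.78 ± 0.48). Camera gave an adjusted p of 2.68e-09 (adjusted p = 0.566 with an estimated correlation). Its library means overlapped between the groups: 0.53, 1.38, 0.97 and 0.22 in libraries 1 to 4 labelled deficient against 0.26, -0.09, 0.38 and -0.54 in the controls (two-sided exact permutation p = 0.0857). Without libraries 2 and 3 the interferon mean was 0.34 and the inflammatory mean 0.46, both still called.

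The list of granulocyte and mast cell markers was not called (8 of 15 negative, mean -0.57, adjusted p = 0.362), with list means of -0.19, -0.62, -0.66 and -0.41 in libraries 1 to 4 labelled deficient against 0.26, -0.34, -0.57 and 0.66 in the controls. Its 4 members with the smallest p, Cpa3 (-2.05 ± 0.49), Tpsb2 (-2.22 ± 0.53), Cma1 (-2.15 ± 0.56) and Mcpt4 (-2.53 ± 0.74), encode mast cell granule proteases. They lay below every control in all 4 libraries labelled deficient and passed when adjusted over the list alone, against 0 over all genes. No separate mast cell list was tested, and Kit, a receptor of mast cells and other cells that was also chosen after its value was seen, was at 0.64 ± 0.47. Erythroid markers were called lower (6 of 7 negative, adjusted p = 0.00887, or 0.566 with an estimated correlation). Their library means overlapped, with library 3 labelled deficient at -0.03, within the control range (two-sided exact permutation p = 0.0857). When adjusted over the list alone 5 erythroid markers passed, 4 lower and 1 higher, against 0 over all genes. Among the lower were the globins Hba-a2 (-0.91 ± 0.18), Hbb-bs (-0.79 ± 0.17) and Hbb-bt (-0.88 ± 0.26). The globin genes are close copies whose reads the counting could split.

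Hormone-responsive genes did not move as one group. Among 30 progesterone-responsive genes 14 were positive and 16 negative, and the list was not called (adjusted p = 0.493). Its mean was 0.17, its median -0.02 and the camera direction lower, so these differ in sign. The library means were 0.55, -0.68, -0.40 and 0.14 in libraries 1 to 4 labelled deficient, against -0.21 to 0.18 in the controls. Zbtb16 (-0.84 ± 0.15) and Cited2 (-0.80 ± 0.18) passed when adjusted over the list alone, against 0 over all genes. Estrogen-responsive genes were called higher (19 of 24 positive, mean 1.16, adjusted p = 0.0164; adjusted p = 0.651 with an estimated correlation). Of these, 7 passed when adjusted over the list alone against 0 over all genes, in both directions: Muc1, a surface mucin, at 2.21 ± 0.61 and Wnt5a at 0.85 ± 0.18, but the growth factors Fgf9 at -1.92 ± 0.41 and Tgfa at -0.90 ± 0.20. The list means were 1.93 and 1.14 in libraries 2 and 3 labelled deficient and 0.22 and 0.19 in libraries 1 and 4. Control library 2 lay at 0.62, above the latter, and control library 1 at -0.48 (two-sided exact permutation p = 0.143). Without libraries 2 and 3 labelled deficient the adjusted p was 0.57. Decidualization genes (13 of 23 negative, adjusted p = 0.468) and steroid receptors and metabolism (10 of 20 negative, adjusted p = 0.546) were not called. In the latter Srd5a1 (-1.91 ± 0.46), Hsd11b1 (-2.21 ± 0.60) and Hsd11b2 (0.79 ± 0.21), enzymes of steroid conversion, passed when adjusted over the list alone, against 0 over all genes.

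Of the markers of other cell types, the epithelial, lymphatic and pericyte lists were called, and none of these 3 calls held without libraries 2 and 3 labelled deficient. Epithelial markers were called higher (15 of 20 positive, mean 0.51, adjusted p = 0.0243; adjusted p = 0.651 with an estimated correlation), with list means of 0.95 and 0.76 in libraries 2 and 3 and -0.10 and 0.00 in libraries 1 and 4, and the mean was -0.06 without both. The call was also lost without library 2 alone (mean 0.30, adjusted p = 0.152) or library 3 alone (mean 0.41, 0.111). Lymphatic markers (mean -0.37, adjusted p = 0.0168; adjusted p = 0.651 with an estimated correlation) and pericyte markers (-0.19, adjusted p = 0.0308; adjusted p = 0.656 with an estimated correlation) were called lower, with means of -0.20 and 0.09 and adjusted p of 0.41 and 0.451 without libraries 2 and 3. The lymphatic call was lost without control library 1 (mean -0.16, adjusted p = 0.158) or library 3 labelled deficient (mean -0.33, 0.0585). The pericyte call was lost without control library 3 (mean -0.16, adjusted p = 0.0834) or library 2 (-0.04, 0.394) or 3 (-0.14, 0.121) labelled deficient. It was also lost with library totals as the scaling (0.055), although the mean did not shrink (-0.22). Endothelial (adjusted p = 0.53), stromal fibroblast (0.546), uterine gland (0.546), mesothelial (0.107), adipocyte (0.236), Schwann cell (0.595) and ovary or oviduct markers (0.371) were not called. Endothelial markers were called lower without library 1 labelled deficient (adjusted p = 0.0112) and higher without libraries 2 and 3 (mean 0.20, 0.00124), and mesothelial markers were called lower without control library 3 (0.0122), without library 2 labelled deficient (0.0495) and without libraries 2 and 3 (0.0222). When adjusted over the list alone 6 markers of these lists passed, against 0 over all genes: Pdpn (-0.36 ± 0.07) of the lymphatic list, Upk1b (-0.68 ± 0.15) and Wt1 (-0.76 ± 0.18) of the mesothelial list, Pparg (0.78 ± 0.15) of the adipocyte list, Cnp (1.06 ± 0.26) of the Schwann cell list and Lif of the gland list.

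Extracellular matrix genes ranked higher as a list, though its library means overlapped between the groups. Library 4 labelled deficient lay at 0.06 and control library 2 at 0.17 (two-sided exact permutation p = 0.0571). Of 35 tested genes 25 had positive differences with a mean of 0.26 and an adjusted p of 0.00234 (adjusted p = 0.566 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Loxl1 (0.69 ± 0.17) and Loxl2 (0.99 ± 0.29), which cross-link collagen, and Col6a2 (0.67 ± 0.21) had small p-values. Cholesterol synthesis (19 of 20 positive, adjusted p = 0.006; adjusted p = 0.651 with an estimated correlation) rested on library 2, whose list mean was 1.53 against 0.12, 0.21 and 0.04 in libraries 1, 3 and 4, and without it the mean fell from 0.66 to 0.13 and the adjusted p was 0.247. Cell cycle genes (27 of 30 positive, mean 0.55, adjusted p = 0.026; adjusted p = 0.656 with an estimated correlation) and nuclear oxidative phosphorylation genes (25 of 28 positive, mean 0.11, adjusted p = 0.0288; adjusted p = 0.656 with an estimated correlation) were called higher, and neither was called without library 2 (means 0.18 and 0.05, adjusted p = 0.694 and 0.267) or without control library 1 (means 0.37 and 0.06, adjusted p = 0.281 for each). The cell cycle list was also not called without library 1 of the group labelled deficient (adjusted p = 0.248), although its mean stayed near that of all libraries (0.48), nor the oxidative phosphorylation list with library totals as the scaling (mean 0.06, adjusted p = 0.0805). No member of these 3 lists passed when adjusted over the list alone or over all genes in edgeR. Library means overlapped between the groups in the cholesterol, cell cycle and oxidative phosphorylation lists (two-sided exact permutation p = 0.143, 0.4 and 0.229). The cell cycle means were 0.82, 1.33, 0.07 and -0.55 in libraries 1 to 4 labelled deficient against -0.66, 0.35, -0.09 and 0.40 in the controls. Glycolysis and hypoxia genes (adjusted p = 0.0681, but 0.0447 without library 1 and 0.0206 without library 3 labelled deficient) and immediate early and heat shock genes (0.603) were not called. In the former Hk2 (1.37 ± 0.26) and Ldha (0.75 ± 0.21) lay above the controls and Slc2a1 (-0.76 ± 0.18) and Bnip3 (-0.62 ± 0.12) below, and these 4 passed when adjusted over the list alone, against 0 over all genes.

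In all, camera called 17 of 30 lists (10 higher, 7 lower) with a preset correlation of 0.01, 0 with an estimated correlation, and 11 without libraries 2 and 3. The rotation test fry called 0 lists for a shared direction and 13 for change in either direction.

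**Figure D2:**
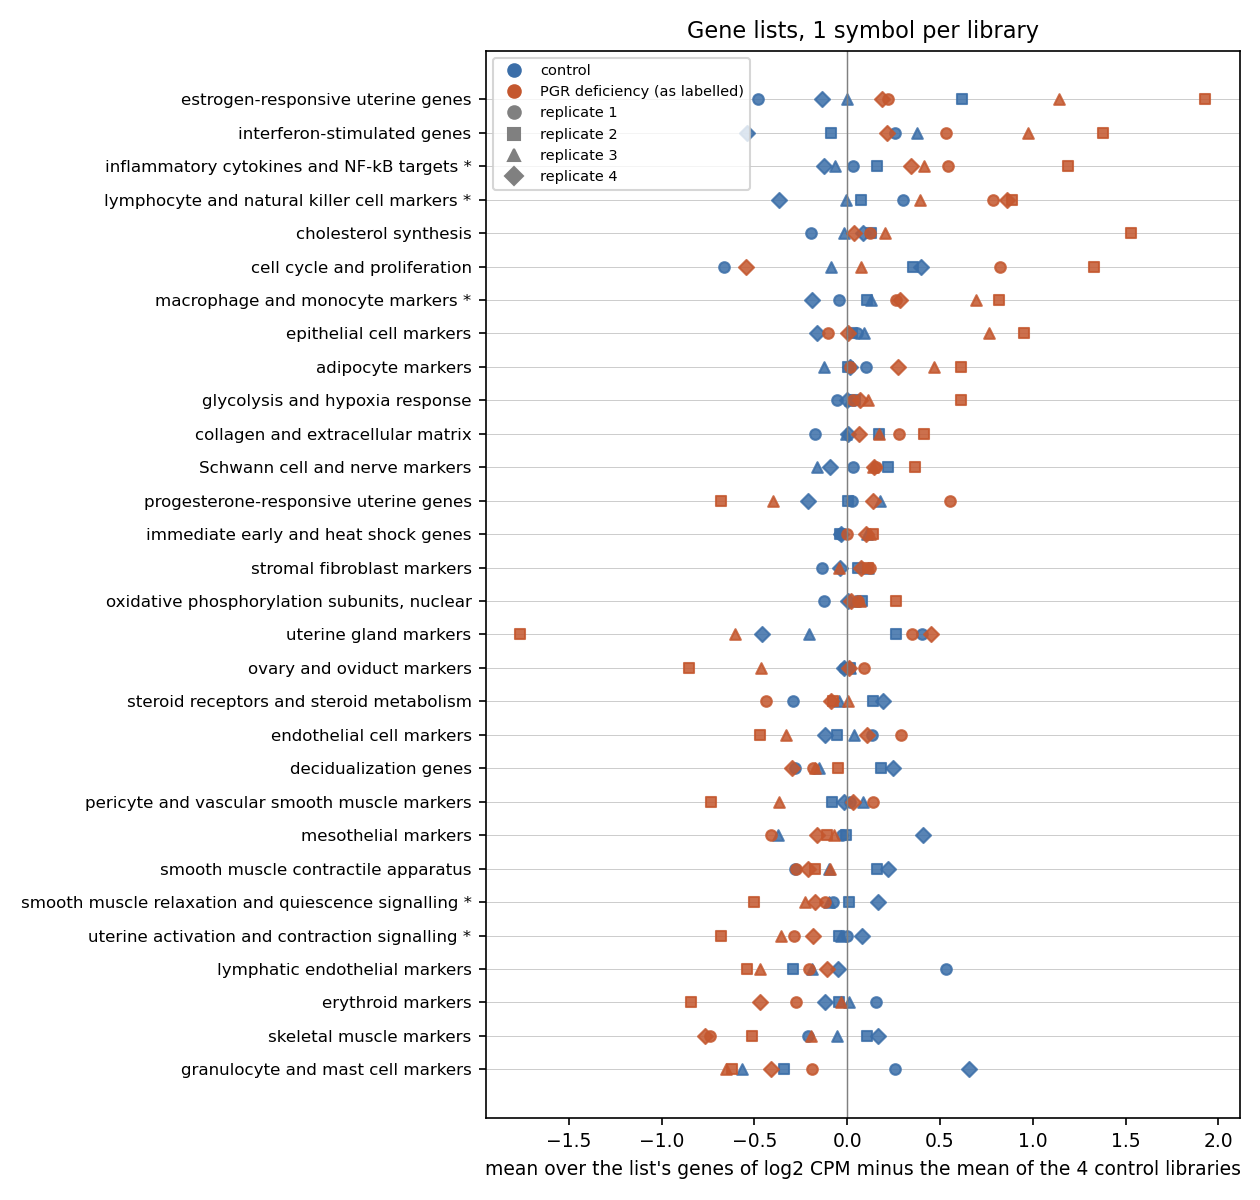
Each of 30 gene lists, with the horizontal axis giving the mean over its genes of log2 CPM minus the mean of the 4 controls; symbols are libraries, colored by group and shaped by replicate number, and asterisks mark the 5 lists whose means do not overlap between groups. Libraries 2 and 3 labelled deficient lie farthest out for estrogen-responsive genes, at 1.93 and 1.14.

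The libraries labelled deficient were also more unlike each other than the controls were. The first principal component of log2 CPM held 50.5% of the variance and separated the groups (two-sided exact permutation p = 0.0286). Scores ran from -44.3 to -16.5 in the controls and were -0.42, 99.8, 45.4 and -16.3 in libraries 1 to 4 labelled deficient. The gap was narrow, as control library 2 lay at -16.5 and library 4 labelled deficient at -16.3. The second component (19.3%) did not separate the groups (exact permutation p = 0.257).

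**Figure D3:**
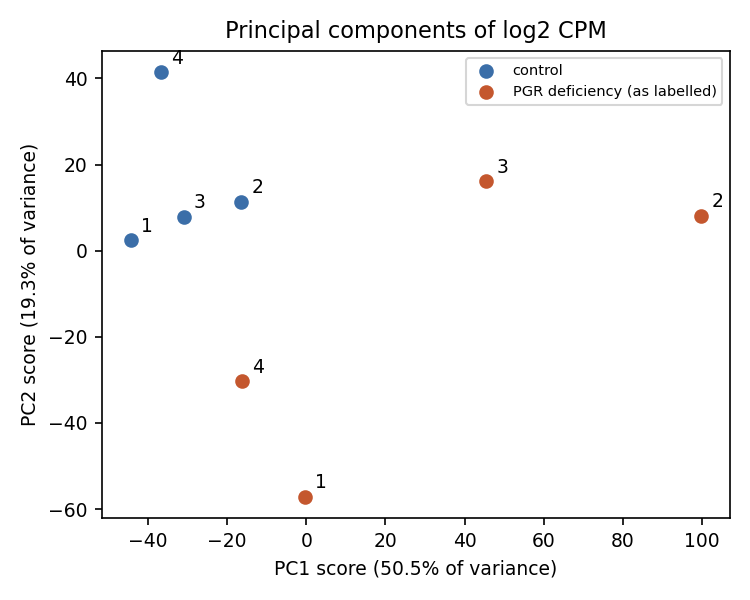
Scores of the 8 libraries on the first component (horizontal, 50.5% of variance) and the second (vertical, 19.3%) of log2 CPM; points are libraries, numbered by replicate and colored by group. Libraries 2 and 3 labelled deficient lie at 99.8 and 45.4 on the first component.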

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

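All tests of explanations and of other splits in this part were chosen or worded after the results they bear on had been seen. The values below are those of 1 library lying far from the other 3 of its group, which chance gives in about 1 of 20 groups: 15 of 290 groups met this, where chance gives about 14, so their number is close to that of chance, though the values are not independent of each other.

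Library 2 labelled deficient accounted for 10 of the 15. In log2 CPM it had Angpt2 at 3.21, Higd1b at 1.66, Cpa3 at -0.65, Cma1 at -1.69, Sdhb at 6.75, Hk2 at 6.36 and Sqle at 5.92. Its list means, as log2 differences from control, were 0.37 for Schwann cell and nerve markers, 0.61 for glycolysis and hypoxia and 1.53 for cholesterol synthesis. Library 3 labelled deficient had Fgf9 at 1.88. Among the controls, library 2 had Actn1 at 8.61, library 4 had Zbtb16 at 7.84, library 1 had Lyve1 at 6.35 and library 3 had a mean of 0.108 for immediate early and heat shock genes.

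The first pattern is that Pgr was not lower in the libraries labelled deficient. Whether 1 control was swapped with 1 library labelled deficient is not decided by the number of small p-values. Over the 16 possible exchanges, at most 3469 genes had an unadjusted p under 0.05, below the 4372 of the labels as given. Libraries could differ in more than Pgr, so the true split need not give the most such genes. Exchanging the labels of all libraries would give the same count. Pgr reads from other cells, or from exons left in place, cannot be told apart from intact Pgr in muscle, since the table holds whole-gene counts of mixed tissue; the lower bound of the fold was 0.950. A deletion limited to muscle therefore remains an open and untested reading.

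The second pattern is that libraries 2 and 3 labelled deficient stand apart. More glandular epithelium as the whole cause is argued against, since 5 of 16 gland markers (Spink3, Prss28, Prss29, Sult1d1 and Lgr5, named after their values were seen) lay below the lowest control in both. Of the other gland markers, Lif and Cxcl17 lay above the highest control in both. More luminal epithelium stays open: 14 of 20 epithelial markers lay above the highest control in both and 0 below the lowest. Handling or RNA stress also cannot be told apart, because the immediate early and heat shock mean was at least 0.121 in both, barely past the highest control at 0.108. An estrogen-like state cannot be told apart either. The estrogen-responsive list of both libraries lay at percentile 100 of 10000 random lists matched on expression, but so did that of control library 2, and control library 1 lay at 0. The measure is thus saturated, and the high list means had been seen before, so the percentiles decide nothing.

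The third pattern is that macrophage and lymphocyte lists were higher, while the third immune list, of granulocyte and mast cell markers, had a mean of -0.57 and was not called. A smaller share of the main cell types would raise all minor types alike. These lists did not rise alike: the mean of the macrophage and lymphocyte lists rose above that of the endothelial, lymphatic and pericyte lists by 0.85. The SD was 0.20 in controls and 0.44 in the other group (two-sided exact permutation p = 0.0286, the smallest possible). The directions of these lists had been seen before, so this p-value was close to given and adds no evidence against that explanation. Of the 0.85, 0.22 is a fall of the vascular lists, which lay at -0.58 and -0.39 in libraries 2 and 3 labelled deficient. Libraries 1 and 4, with vascular lists at 0.07 and 0.01, still lay at 0.45 and 0.56, above the highest control at 0.23. With the granulocyte and mast cell list included the difference was 0.48 (SD 0.11 in controls, 0.34 in the other group; exact permutation p = 0.0286). Libraries 2 and 3 were not alone in lying high. The macrophage means of libraries 1 and 4 were 0.26 and 0.28 against at most 0.13 in a control. Their lymphocyte means were 0.79 and 0.86 against at most 0.30. This restates the separation of the groups by both lists, already given above, and is no further test. Camera without libraries 2 and 3 gave adjusted p of at most 0.00183 for both with its preset correlation, but over all libraries neither was called with an estimated correlation (adjusted p = 0.517 and 0.488). More immune cells, or higher expression per cell, both remain open.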

How the results depend on the processing

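The fit with legacy=FALSE, DESeq2 without each library, and the runs without libraries 2 and 3 labelled deficient were chosen after seeing the data. The count of genes called depends on the test: 0 in edgeR (4372 at an unadjusted p under 0.05), 2488 in DESeq2, 2 in limma-voom and 3 with legacy=FALSE (Cabp7 and Ecel1 higher, Slc10a2 lower). The cause was not tested, though on simulated counts DESeq2 made 51 false calls and edgeR 5. The edgeR count was also 0 under the other scalings, filters and robust=TRUE. It ran from 0 to 2 when each library was left out, with 2 without control library 2. The test against a fold of 1.2 is stricter than the main one, so its 0 says nothing further. With the replicate number as a block edgeR called 23 (19 higher, 4 lower). In their deviations from the group mean, same-numbered libraries correlated at 0.223, 0.289, -0.009 and -0.107. Not every library correlated best with its own number. These few values show no clear pairing by number but cannot exclude it, so pairing is left open.

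Genes at an unadjusted p under 0.05 ran from 2896 (without control library 4) to 5471 (without library 4 labelled deficient). DESeq2 calls ran from 927 to 3961 on leaving out the same libraries, with 1328 without control library 1, 1531 without library 2 labelled deficient, and 1461 without libraries 2 and 3, of which 918 were among the 2488. These runs use fewer libraries.

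Lists called were 17, with 13 to 18 on leaving out each library, 15 with library totals (pericyte lost at adjusted p = 0.055 with its mean at -0.22 against -0.19, and oxidative phosphorylation at 0.0805 with 0.06 against 0.11), 16 with the block (cell cycle lost at 0.0576, mean 0.44 against 0.55), 11 without libraries 2 and 3, and 0 with an estimated correlation or fry. Without libraries 2 and 3 the list means of epithelial (-0.056), endothelial (0.20), pericyte (0.090), gland (0.27) and ovary or oviduct markers (0.12) and Krt19 (-0.28) changed sign among the results reported, the gland and ovary lists from means near 0 and not called either way; the cause was not tested. Pgr stayed between 0.09 and 0.25, never past the threshold. Of 114 named genes, 78 passed in DESeq2 and none in the edgeR and voom alternatives tried (4372 at an unadjusted p under 0.05 in edgeR overall). Scaling moved the median of all genes by less than 0.1. Depth was even, so it limits mainly genes at a few counts, such as Cabp7.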

Other observations

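The tests in this part, including those on other splits of the libraries, were chosen after the results they bear on had been seen.

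The genes with the smallest p included Sesn1 and Irs2, which are known targets of FoxO transcription factors, and this prompted a separate list of 18 other FoxO targets. In these, 14 were lower and 4 higher, and 10 had an unadjusted p under 0.05, as did 24.8% of all tested genes. Pik3ip1, an inhibitor of PI3 kinase, had a log2 difference of -0.90 ± 0.21 (SE), Txnip of -0.68 ± 0.15 and the cell cycle inhibitor Cdkn1b of -0.38 ± 0.09. The list mean was lower by -0.29 (SD 0.09 in controls, 0.07 in the other group; two-sided exact permutation p = 0.0286, the smallest possible), at -0.35, -0.32, -0.20 and -0.31 in libraries 1 to 4 labelled deficient. Of 10000 random lists matched on expression, 0.06% fell as far, though 7.83% of them also separated the groups downward. Genes of the random lists were drawn singly, so they need not move together as the genes of a pathway may, and the 0.06% can be too small. The FoxO list was not tested with camera. Lower FoxO target expression is a hypothesis that may be worth testing in other samples, since it was found and tested on the same libraries.

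The labelled split ranked first for small p-values, which random placement gives in 1 of 35 cases, the least possible. The counts below share the same libraries and are not separate evidence, so chance is not excluded. Any other difference that runs along the labels would rank the same way. Of 35 splits into 4 and 4, 1 (the real one) gave as many genes at an unadjusted p under 0.05 (4372, highest other 3469), 1 gave as many separated genes (2868, highest other 1794) and 1 as many DESeq2 calls (2488, highest other 903). For lists called by camera chance cannot be excluded either, since 4 splits reached 17, the highest of the others also being 17. For genes called by edgeR the real count was 0 (4372 at an unadjusted p under 0.05; 2488 in DESeq2, 2 in limma-voom), so that all 35 splits giving as many was certain beforehand and says nothing about chance; the highest other was 5.

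The split with 5 calls set libraries 1 and 3 of the controls and 1 and 4 labelled deficient against the rest. It gave 1393 separated genes and 695 DESeq2 calls. The other 5 splits that part libraries 2 and 3 labelled deficient from 1 and 4, each set with other controls, gave 392 to 609 and 14 to 93, so the difference between those libraries does not account for it alone. A structure of the samples across the groups is left open, as the split was picked for having the most edgeR calls and no test allowed for that choice. Its 5 genes, which separate it because they were picked for that, and named after their values were seen, were Slc13a5, Sox2ot, Pacsin3, Slc11a2 and AK165607. Slc13a5, a citrate transporter, measured 27.8, 0.762, 26.3 and 0.437 CPM in control libraries 1 to 4 and 32.6, 0.311, 0.156 and 38.8 CPM in those labelled deficient. No explanation was tested.

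Some genes were near absent from some libraries of both groups and well counted in others, and were also picked after their values were seen. BC018473 had 795, 0, 1213 and 512 counts in the controls and 1, 1532, 876 and 2 in the libraries labelled deficient, and Ccnb1ip1 had 1, 88, 1 and 144 against 0, 1, 2 and 71. No explanation was tested for these.

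As a further test, variants carried along with the Pgr locus could leave differences in neighboring genes. Within 20 Mb of Pgr, 9.42% of 138 genes had an unadjusted p of at most 0.01, against 9.08% of the other genes (Fisher's exact p = 0.881, over genes, which are not independent), which gives no sign of such an excess.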
